A study of Rattus norvegicus with 18 samples.

How the data were processed

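The 18 samples were of PC12, a line of rat pheochromocytoma (adrenal gland tumour) cells that responds to nerve growth factor. The groups were serum-grown PC12 cells (the control), serum-grown cells of a PC12 line called PC12-ND6, and PC12-ND6 cells kept without serum for 48 h, with 6 arrays in each of the 3 groups. Per the labels, the series concerned overexpression of NeuroD6, a neuronal basic helix-loop-helix (bHLH) transcription factor, with or without an apoptotic stimulus, and serum was withheld to examine survival. Cells grew at 37 °C on collagen-coated plates in F-12K medium containing horse serum (15%) and fetal bovine serum (2.5%). Total RNA was extracted with a RiboPure kit, and biotin-labelled antisense cRNA was made from 15 µg of it.

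The authors deposited one table of intensities on a linear scale, with 15923 probe sets (the short probes on an array that together measure one transcript) and 1 column per array. MAS5, GCOS and GCRMA are named per the submitters' processing notes, which give no version or role for any of them, so which one made the deposited values is not given in the sources used here. The deposited intensities ran from 0, reached by 20 values, to 12721.4. They were not scaled to a common level, since the mean signal of an array ran from 187.7 to 328.8. The design fixed beforehand allowed for a log2 or a linear table, and the linear branch applied. The values were therefore tested as log2(intensity + 16), which understates the fold change of weakly expressed genes. All fold changes below are on that scale, while signals are means ± SD of the deposited intensities over the 6 arrays of a group.

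The 57 control probe sets of the manufacturer were left out, and the other 15866 were tested without a filter on dim signals. Gene symbols came from a table of the platform's annotation: 12783 probe sets had 1 symbol, 312 had several and 2771 had none there. Symbols were looked up through Entrez identifiers in a gene table of the assembly GRCr8, where 12748 probe sets matched and 0 symbols changed. None was named from a probe set with several symbols. A gene with several probe sets was represented by the one with the highest mean over the 18 arrays, which left 10411 genes. Array annotation of this kind names no genome build, so no coordinates are given.

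Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 18 arrays in 1 fit, group as the only term), two-sided, with Benjamini-Hochberg adjustment over 15866 probe sets and a threshold of 0.05. Each adjusted p for a gene comes from that fit. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 90 tests (30 lists in 3 comparisons). A list's shift is the mean log2 fold change of its genes minus that of the other genes. Camera asks whether a list moved more than the other genes did. With the correlation between genes estimated from the data in place of the preset value, 0 of the 25 calls held, and that p is given with the calls. The estimate used the unscaled deposited values with group as the only term. Differences in brightness, or any others shared by arrays within a group, thus count in it. It ran from 0.018 for Schwann cell and glial markers to 0.684 for the proteasome. It was not repeated after quantile normalization or with a block, so a lost call does not decide whether a list moved. The 25 calls are those of all 3 comparisons together. Counts within a list are given over all probe sets tested. For scale, of all 10411 genes 1221 were called in PC12-ND6 with serum against control and 1001 after serum removal. In PC12-ND6 without serum against control 1828 were called. In the parentheses after them stand the genes higher and lower when adjusted over the list alone, then those after quantile normalization, then the adjusted p of the list where it was not called.

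The genes named were fixed by a rule. It took NeuroD6, the members of the bHLH list past the threshold and a change of 1, the 8 highest and 8 lowest genes of PC12-ND6 with serum against control and of serum removal, and the 4 highest and 4 lowest of the remaining comparison. Those genes had no overlap between the 6 and 6 arrays, a change of at least 1, and a higher group above the median signal. From each list it took up to 4 called members by size of change. Lists are illustrated in that order by fewer members where the rest are counted.

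The deposited columns were compared pairwise, and 0 of 153 pairs of arrays were identical. On the log2 scale after quantile normalization, correlations within groups ran from 0.971 to 0.9911. The arrays of replicates 1 to 3 differed from those of replicates 4 to 6 within every group, although no label names a batch. Values within each of those sets are printed beside the main counts and the list shifts. The alternatives comprised other scalings, pseudocounts of 1 and 64, a floor, a filter on dim probe sets, other variance models, array weights, blocks, and leaving out each array. The blocks of replicates 1 to 3 against 4 to 6, the analyses within each of those sets, and those on the actin ratio were chosen after seeing the data. Because the choice of scaling changed the balance of higher and lower calls, results after quantile normalization of the 18 arrays are given beside the counts.

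The code was tested on simulated arrays made from the measured means and spreads for PC12-ND6 with serum against control, with 15866 probe sets. Of 50 probe sets changed by 1 on the log2 scale it recovered 41, of 50 changed by 2 all 50, and of 50 changed by 0.5 only 2. It made 4 false calls among 15627 unchanged probe sets. The simulated noise was independent between probe sets apart from an offset per array. In the measured arrays genes varied together and the 2 sets of replicates differed, so that number of false calls may not hold there. For array data the number of arrays limits the precision. Exact permutation tests of array measures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.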

Results

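Expression was measured in 3 groups of 6 arrays: PC12 cells in serum, PC12-ND6 cells in serum, and PC12-ND6 cells after 48 h without serum. The mean signal of an array was 249 ± 41.6 (SD, n = 6) in the control, 229 ± 55.1 in PC12-ND6 with serum and 244 ± 24.6 without serum, with no difference past an exact permutation test (two-sided, p = 0.429 with serum against control and 0.431 for serum removal). The ratio of the 3' to the 5' actin probe set, a measure of RNA integrity, was 3.40 ± 1.72 in the control, 4.05 ± 2.29 in PC12-ND6 with serum and 2.70 ± 0.454 without serum (exact permutation p = 0.63 and 0.264 for the same comparisons). It was higher in replicates 4 to 6 than in replicates 1 to 3, at 4.64 against 2.15 in the control, 5.78 against 2.31 in PC12-ND6 with serum, and 2.97 against 2.44 without serum. No label says that the 6 replicates of a group came from separate cultures, so the p-values measure only the spread between samples. Neurod6 itself, the overexpressed gene, was not measured under the annotation used, since 0 probe sets carried its symbol. The labels name 1 PC12-ND6 line and no vector control, so NeuroD6 and the line that carries it could not be told apart. A serum-deprived control group is not among the groups analysed here, so whether NeuroD6 alters the response to serum removal could not be tested. PC12-ND6 with serum is labelled as 0 h and PC12-ND6 without serum as 48 h, and no PC12-ND6 group was in serum at 48 h. Effects of serum removal and of the 48 h in culture could therefore not be told apart. Below, serum removal is the name of that comparison.

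The comparison of PC12-ND6 with control cells in serum asks how the NeuroD6 line differs from its parent while both grow. Cell division genes were lower in PC12-ND6 than in the control. All 39 measured mitosis genes fell, and so did 31 of 37 DNA replication genes (35 adjusted over the list alone, 32 after quantile normalization). Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, went from a signal of 1199 ± 530 to 108 ± 34.1, and Top2a, a topoisomerase of dividing cells, from 443 ± 212 to 33.6 ± 10.4. With the preset correlation, endoplasmic reticulum chaperones were higher as a group (7 of 30 genes up), with Hspa5 (BiP) at 3513 ± 770 against 1781 ± 900. Glycolysis (8 of 26 down), fatty acid synthesis (7 of 23 down) and catecholamine genes (7 of 22 down) were lower. None of these 4 group calls held with an estimated correlation (adjusted p = 0.999 for each), nor did those of mitosis (0.0662) and DNA replication (0.351).

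On the scale used, the largest increase was that of S100a6, a calcium-binding protein and one of the fixed fibroblast markers, from 122 ± 31.3 to 2214 ± 1092 (log2 fold change 3.88, SE 0.27, adjusted p = 3.71e-09). The Hippo pathway kinase Lats2 rose from 8.2 ± 6.4 to 243 ± 73.0 (3.41, SE 0.18, adjusted p = 8.1e-11). Podocalyxin (Podxl), a sialomucin of the cell surface, rose from 16.5 ± 6.0 to 251 ± 59.0. Heme oxygenase 1 (Hmox1), which degrades heme, rose from 488 ± 201 to 2891 ± 825. Mat1a, which makes S-adenosylmethionine, rose by 2.34 on the log2 scale and Fam171b by 2.26. Among transcription factors, Myc rose from 103 ± 40.4 to 538 ± 153 (2.23, SE 0.24, adjusted p = 1.02e-06), and the stress-induced Atf3 from 14.4 ± 15.4 to 114 ± 25.3.

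Among the largest decreases, Chrna3, a subunit of the neuronal nicotinic acetylcholine receptor, fell from 356 ± 61.3 to 3.3 ± 2.4 (log2 fold change −4.26, SE 0.13, adjusted p = 2.66e-14). The focal adhesion protein tensin 1 (Tns1) went from 347 ± 110 to 3.4 ± 1.7, the hedgehog co-receptor Boc from 276 ± 68.6 to 2.5 ± 1.4, and the small GTPase Rras2 from 369 ± 54.0 to 14.2 ± 7.1. Thy1, a surface glycoprotein of neurons, fell from 1794 ± 246 to 115 ± 41.0. Uchl1, a ubiquitin hydrolase abundant in neurons, fell from 1586 ± 155 to 109 ± 22.9 (−3.69, SE 0.15, adjusted p = 9.76e-13). Troap fell from 235 ± 109 to 4.5 ± 1.2. In PC12-ND6 Chrna3, Tns1, Boc, Rras2 and Troap lay under a signal of 16, as did Lats2, Atf3 and Fam171b in the control, so the size and order of their changes depend on the pseudocount. With Ube2c these were 16 genes by the naming rule, which required no overlap between the 6 and 6 arrays. The change in replicates 1 to 3 and in replicates 4 to 6 was 4.28 and 3.48 for S100a6, and −3.90 and −3.48 for Uchl1.

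**Figure D1:**
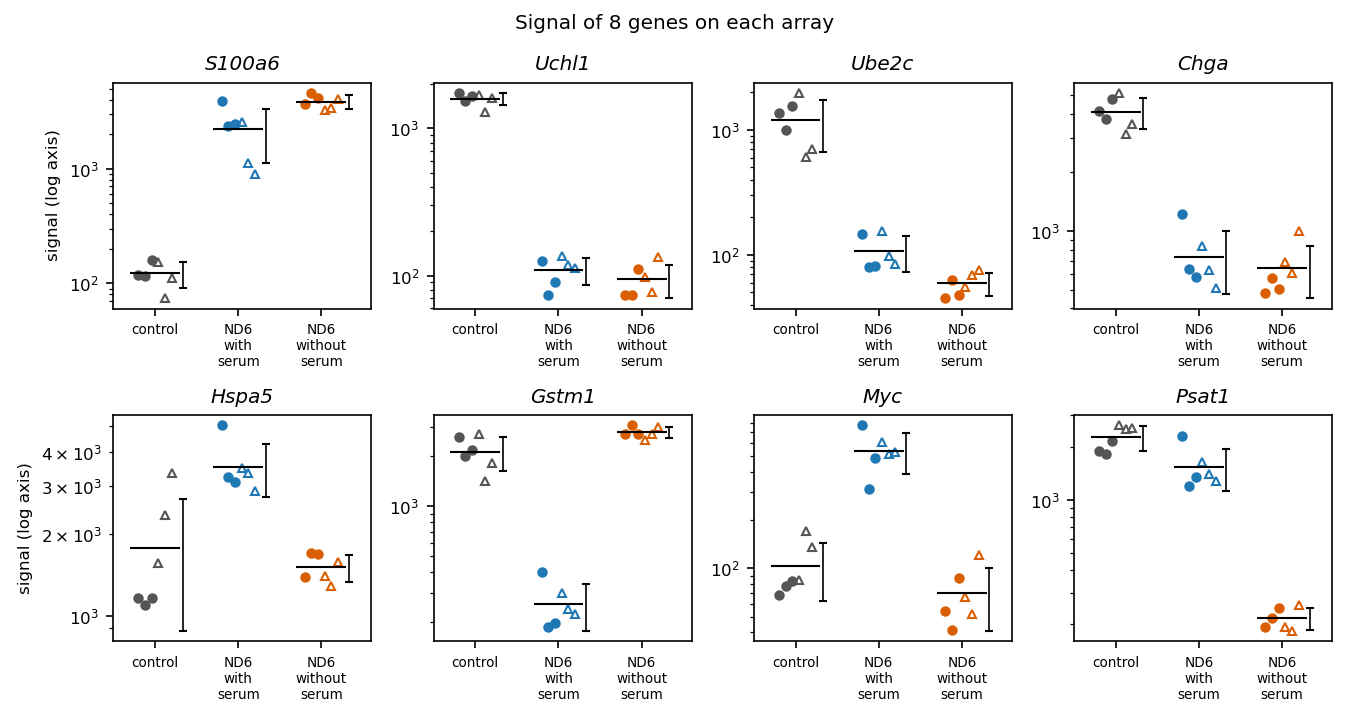
Signal of S100a6, Uchl1, Ube2c, Chga, Hspa5, Gstm1, Myc and Psat1 on each of the 18 arrays (log axis, deposited intensity), with filled circles for replicates 1 to 3, open triangles for replicates 4 to 6, black lines for group means and bars for 1 SD. Uchl1 lies near 1586 in the control and near 109 in PC12-ND6 with serum, Gstm1 returns from 258 with serum to 2799 without it, and Psat1 falls from 1530 with serum to 214 without it.

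In the mitosis list the shift was −1.77 on the log2 scale (camera adjusted p = 1.97e-51, adjusted p = 0.0662 with an estimated correlation), −2.04 in replicates 1 to 3 and −1.50 in replicates 4 to 6. The DNA replication list shifted by −0.85 (adjusted p = 1.5e-23, and adjusted p = 0.351 with an estimated correlation), −0.997 and −0.70 in those sets. Thymidine kinase Tk1 fell from 402 ± 199 to 69.8 ± 15.5, and the helicase subunit Mcm5 from 536 ± 170 to 174 ± 40.8. Tk1 lies in a stretch of neighbouring genes that were lower together in PC12-ND6. In the list of G1 control and growth arrest, 8 of 37 genes were higher and 5 lower (8 and 5 adjusted over the list alone, 15 and 7 after quantile normalization). Gadd45a and cyclin G1 (Ccng1) were among those higher, at 270 ± 114 against 108 ± 62.6 and at 1300 ± 336 against 545 ± 136. This list shifted by 0.21 (adjusted p = 0.0297, and adjusted p = 0.999 with an estimated correlation). The call ended after median centring (adjusted p = 0.0633) and in replicates 4 to 6 (0.11 there, adjusted p = 0.165, against 0.31 in replicates 1 to 3).

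Of the 30 endoplasmic reticulum chaperone genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone, 18 and 1 after quantile normalization), and the list shifted by 0.41 (adjusted p = 2e-06, and 0.999 with an estimated correlation). Besides Hspa5 (log2 fold change 1.08, SE 0.23, adjusted p = 0.00251), Pdia2 stood at 13.6 ± 7.2 against 0.7 ± 0.4, a change whose call ended when each array was floored at its 20th percentile (0.29, adjusted p = 0.214). Of 40 cytosolic heat shock genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, 18 and 0 after quantile normalization), with a list shift of 0.28 (adjusted p = 0.00157, and 0.999 with an estimated correlation). Hspb1 rose from 632 ± 144 to 2367 ± 633 (1.87, SE 0.17, adjusted p = 1.08e-07). Hspa1a stood at 335 ± 112 against 171 ± 108 (1.07, adjusted p = 0.0185), and its call ended without control replicate 3 (0.88, adjusted p = 0.0524). Of 51 lysosome and autophagy genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, 13 and 1 after quantile normalization), among them the cathepsin Ctsl, at 1555 ± 454 against 764 ± 418, and the mannosidase Manba, at 49.9 ± 20.1 against 18.9 ± 7.2. The lysosome list shifted by 0.18 (adjusted p = 0.0363, and 0.999 with an estimated correlation). Of 45 ribosomal protein genes 3 rose and 0 fell (3 and 0 adjusted over the list alone, 10 and 0 after quantile normalization), and the list shifted by 0.22 (adjusted p = 0.00306, and 0.999 with an estimated correlation). The 3 were Rpl22, at 4306 ± 978 against 1763 ± 426, Rpl14 and Rpsa, and the latter pair lie in a stretch of neighbouring genes that were higher together in PC12-ND6.

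The chaperone, lysosome and ribosomal shifts were larger in replicates 1 to 3 than in replicates 4 to 6, at 0.57 and 0.25 for the endoplasmic reticulum, 0.37 and 0.19 for heat shock, 0.26 and 0.10 for the lysosome, and 0.32 and 0.11 for ribosomal proteins. That difference was not tested for lists. By limma 0 probe sets passed the threshold for it, but 2392 of 15866 had an unadjusted p under 0.05, above the 5% that chance gives. The lack of calls thus does not show that the 2 sets of replicates agree. In replicates 4 to 6 alone the lysosome (adjusted p = 0.426) and ribosomal (adjusted p = 0.31) calls ended. So did those of Hspa5 (0.48, adjusted p = 0.193), Hspa1a (0.27, adjusted p = 0.443), Ctsl (0.43, adjusted p = 0.301), Manba (0.63, adjusted p = 0.0863), Gadd45a (0.63, adjusted p = 0.189), Rpl14 (0.33, adjusted p = 0.241) and Rpsa (0.43, adjusted p = 0.116). With unequal variances the calls of Hspa5 (adjusted p = 0.107), Hspa1a (0.223), Ctsl (0.133), Gadd45a (0.088) and Rpl14 (0.088) ended as well, and in the fit of only the 2 groups that of Hspa1a (0.0755). The lysosome call also ended without control replicate 2 (adjusted p = 0.0753), control replicate 3 (0.0696), PC12-ND6 with serum replicate 1 (0.0954) or replicate 4 (0.0561). Array weights ended the lysosome (adjusted p = 0.0569) and ribosomal (adjusted p = 0.348) calls, and the most variable probe set per gene ended the lysosome call (adjusted p = 0.0902).

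In fatty acid synthesis 0 of 23 genes rose and 7 fell (0 and 10 adjusted over the list alone, 2 and 9 after quantile normalization). The desaturase Scd fell from 257 ± 68.4 to 87.9 ± 38.5, and fatty acid synthase (Fasn) from 1584 ± 224 to 662 ± 129. In glycolysis 0 of 26 genes rose and 8 fell (0 and 10 adjusted over the list alone, 3 and 8 after quantile normalization). The lactate exporter Slc16a3 fell from 463 ± 98.9 to 119 ± 26.5, and phosphofructokinase Pfkl from 672 ± 307 to 270 ± 108. The Pfkl call ended without the 4 arrays of highest actin ratio (−1.221, adjusted p = 0.0887) and with unequal variances (adjusted p = 0.0708). Fasn and Slc16a3 lie in the same stretch of lower neighbouring genes as Tk1. The fatty acid list shifted by −0.28 (adjusted p = 0.00838, and 0.999 with an estimated correlation), by −0.36 in replicates 4 to 6 and by −0.21 in replicates 1 to 3, where its call ended (adjusted p = 0.0995). The glycolysis list shifted by −0.27 (adjusted p = 0.0128, and 0.999 with an estimated correlation), −0.27 and −0.26 in the 2 sets of replicates. Of 22 genes of catecholamine synthesis and sympathoadrenal identity, 0 rose and 7 fell (2 and 9 adjusted over the list alone, 4 and 8 after quantile normalization). The vesicular monoamine transporter Slc18a1 fell from 977 ± 534 to 240 ± 184, and monoamine oxidase A (Maoa) from 268 ± 42.1 to 55.0 ± 19.2. The Slc18a1 call ended with unequal variances (−2.04, adjusted p = 0.113). The shift of the list was −0.32 (adjusted p = 0.035, and 0.999 with an estimated correlation), −0.33 and −0.30 in the 2 sets. The catecholamine call ended in 5 of 18 alternative settings, with an adjusted p up to 0.248 in replicates 4 to 6, and without control replicate 3 (0.0697) or PC12-ND6 with serum replicate 5 (0.0556).

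The other neuronal lists were not called as groups, although single members changed strongly. Of 24 dense-core granule genes 0 rose and 4 fell (0 and 4 adjusted over the list alone, 1 and 4 after quantile normalization, list adjusted p = 0.199). Chromogranin A (Chga) fell from 4086 ± 754 to 734 ± 261, and the neurosecretory protein Vgf from 632 ± 286 to 150 ± 46.0. Among 37 neurite and cytoskeleton genes 3 rose and 9 fell (3 and 10 adjusted over the list alone, 8 and 9 after quantile normalization, list adjusted p = 0.854). The adhesion molecule L1cam fell from 1330 ± 496 to 464 ± 226, while the growth cone protein Gap43 rose from 5.0 ± 3.9 to 46.5 ± 18.6. Of 38 synaptic vesicle genes 4 rose and 4 fell (4 and 5 adjusted over the list alone, 5 and 5 after quantile normalization, list adjusted p = 0.73). Of 42 ion channel and acetylcholine receptor genes 1 rose and 5 fell (1 and 7, 2 and 7, 0.73). Of 18 bHLH genes 1 rose and 1 fell (1 and 2, 1 and 2, 0.73). Of 44 growth factors and receptors 5 rose and 4 fell (5 and 4, 5 and 4, 0.654).

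Apart from the chaperone and heat shock lists, stress and survival lists were not called either in this comparison. Of 56 antioxidant genes 1 rose, Hmox1, and 6 fell (1 and 6 adjusted over the list alone, 13 and 6 after quantile normalization, list adjusted p = 0.73), led by the glutathione transferase Gstm1, which fell from 2129 ± 495 to 258 ± 80.7. Of 37 ATF4 and amino acid stress genes 5 rose and 3 fell (5 and 5 adjusted over the list alone, 6 and 3 after quantile normalization, list adjusted p = 0.73). Of 35 pro-apoptotic genes 2 rose and 1 fell (2 and 1, 7 and 2, 0.19). Of 29 anti-apoptotic genes 3 rose and 3 fell (3 and 4, 5 and 3, 0.698). Of 42 immediate early genes 5 rose and 3 fell (5 and 4, 6 and 4, 0.088). Of 22 cholesterol genes 0 rose and 4 fell (0 and 5, 2 and 4, 0.237). Of 35 interferon genes 3 rose and 0 fell (3 and 0, 7 and 1, 0.484). Of 46 mitochondrial biogenesis genes 0 rose and 3 fell (0 and 1, 4 and 3, 0.961). By limma, 0 of 69 oxidative phosphorylation genes (adjusted p = 0.423) and 0 of 30 proteasome genes (0.662) passed the threshold as deposited, and after quantile normalization 2 of the former rose and 5 fell, and 4 of the latter rose. The markers of other cell types were not called as groups. Among 43 fibroblast and matrix markers 2 rose and 4 fell (2 and 5 adjusted over the list alone, 4 and 5 after quantile normalization, list adjusted p = 0.73). Among 20 Schwann cell and glial markers 0 rose and 1 fell (0 and 1, 0 and 1, 0.714). Among 32 leukocyte and endothelial markers 0 rose and 3 fell (0 and 2, 2 and 4, 0.714). Among 15 adrenal cortex markers 0 changed as deposited and 1 rose after quantile normalization (0.73). Some of these lists were called in other settings: the immediate early list with the most variable probe set per gene (adjusted p = 0.04) and in replicates 1 to 3 (0.046), the ATF4 list in replicates 1 to 3 (0.033), and the cholesterol list in replicates 4 to 6 (0.0475). The oxidative phosphorylation list was lower with array weights (−0.195, adjusted p = 0.00144) and without PC12-ND6 with serum replicate 1 (0.0164), and the proteasome list higher after quantile normalization with the actin ratio (0.0376).

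Over all 15866 probe sets, 423 were higher and 1186 lower in PC12-ND6 with serum than in the control, or 1715 and 1464 after quantile normalization. Higher calls were thus 26.3% of the calls as deposited and 53.9% after quantile normalization, and 1552 probe sets were called in the same direction both ways. With a change of at least 1 on the log2 scale the counts were 121 higher and 385 lower, or 169 and 305 after quantile normalization. The 6 and 6 arrays did not overlap for 685 probe sets (4.32%, where chance gives 0.216%). Within replicates 1 to 3 alone 382 were higher and 415 lower, and within replicates 4 to 6 alone 197 and 1984. Without PC12-ND6 with serum replicate 1, the brightest array at a mean signal of 328.8, the lower count was 1864. That array stood apart from the other 5 of its group for Hspa5 (5021) and Hspb1 (3587), as did control replicate 4 for Vgf (1199) and control replicate 3 for Pdia2 (1.6).

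Serum removal from PC12-ND6 cells addressed how the line responds to a stimulus that can lead to apoptosis. After 48 h without serum the ATF4 and amino acid stress genes were lower: 30 of 37 fell and 1 rose. Psat1, an enzyme of serine synthesis, fell from 1530 ± 403 to 214 ± 30.7, and Chac1, which degrades glutathione, from 1240 ± 224 to 190 ± 47.4. With the preset correlation, endoplasmic reticulum chaperones (3 of 30 genes down), cholesterol genes (3 of 22), mitosis genes (3 of 39) and DNA replication genes (2 of 37) were lower as groups, and glycolysis genes (9 of 26 up) were higher. None of these 5 group calls held with an estimated correlation (adjusted p = 0.999 for each), nor did that of the ATF4 list (0.0662). Gstm1 rose from 258 ± 80.7 to 2799 ± 215, and Myc, which had been higher in PC12-ND6 than in the control, fell from 538 ± 153 to 70.6 ± 29.6.

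The largest increase was that of Gstm1 (log2 fold change 3.41, SE 0.17, adjusted p = 3.34e-10). Filip1l rose from 78.0 ± 22.6 to 805 ± 134 (3.14, SE 0.18, adjusted p = 8.59e-10). The sodium pump regulator Fxyd6 rose from 81.8 ± 17.0 to 653 ± 123, and the ubiquitin ligase Rnf144b from 38.0 ± 9.0 to 314 ± 64.3. Sprr1a, a small proline-rich protein, rose by 2.59 on the log2 scale, and keratin 18 (Krt18) from 249 ± 89.3 to 1197 ± 238. Tmem140 rose by 2.17 on the log2 scale, and ceruloplasmin (Cp), a copper-carrying ferroxidase, by 2.14.

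The strongest decrease was that of the inflammatory caspase Casp4, from 377 ± 105 to 29.4 ± 7.9 (log2 fold change −3.09, SE 0.35, adjusted p = 6.41e-06), followed by Psat1 (−2.72, SE 0.15, adjusted p = 8.14e-10), Myc (−2.69, SE 0.24, adjusted p = 2.23e-07) and Chac1 (−2.62, SE 0.17, adjusted p = 3.85e-09). The transcription factor Atf5 fell from 1991 ± 510 to 372 ± 148, the pseudokinase Trib3 from 1438 ± 354 to 278 ± 28.2, the serine synthesis enzyme Psph from 325 ± 140 to 52.6 ± 14.5, and the secreted stanniocalcin Stc2 from 338 ± 98.6 to 57.5 ± 12.6. The naming rule required no overlap between the 6 and 6 arrays for these 16 genes. Their sizes in the 2 sets of replicates were, for example, 3.45 and 3.36 for Gstm1 and −2.75 and −2.69 for Psat1. Bhlhe40, the bHLH list member past both thresholds, stood at 92.9 ± 31.1 against 42.7 ± 31.7 (1.02, SE 0.29, adjusted p = 0.0311). Its call ended without PC12-ND6 with serum replicate 5 (adjusted p = 0.0857) or 6 (0.0802), or without the serum-free replicate 2 (0.0608), 3 (0.0815) or 6 (0.0807). It also ended in replicates 1 to 3 (0.622, adjusted p = 0.367), without the 4 arrays of highest actin ratio (0.581, adjusted p = 0.192), with unequal variances (adjusted p = 0.184), with a pseudocount of 1 (0.0578) and in the fit of only the 2 groups (0.0545), so this change is weakly supported.

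The ATF4 list shifted by −1.26 (adjusted p = 6.03e-49, and adjusted p = 0.0662 with an estimated correlation), −1.28 in replicates 1 to 3 and −1.24 in replicates 4 to 6. Its counts were the same adjusted over the list alone and after quantile normalization, 1 higher and 30 lower. Of 30 endoplasmic reticulum chaperones 1 rose and 3 fell (1 and 8 adjusted over the list alone, 1 and 15 after quantile normalization). The degradation component Herpud1 fell from 1616 ± 388 to 651 ± 53.8, and Hspa5 from 3513 ± 770 to 1507 ± 172. The chaperone list shifted by −0.38 (adjusted p = 3.43e-06, and 0.999 with an estimated correlation), −0.41 and −0.35 in the 2 sets. Of 22 cholesterol genes 0 rose and 3 fell (0 and 7 adjusted over the list alone, 0 and 10 after quantile normalization), among them Insig1, a regulator of sterol synthesis, from 611 ± 176 to 253 ± 38.1. That list shifted by −0.35 (adjusted p = 9.99e-05, and 0.999 with an estimated correlation), −0.36 and −0.34 in the 2 sets. Of 39 mitosis genes 0 rose and 3 fell (0 and 3 adjusted over the list alone, 0 and 10 after quantile normalization), led by Hmmr, which fell from 69.5 ± 10.9 to 21.2 ± 5.4, and Cdkn3, from 144 ± 37.5 to 59.2 ± 13.1. In replicates 4 to 6 the Cdkn3 call ended (−0.909, adjusted p = 0.0922). Mitosis shifted by −0.38 (adjusted p = 1.4e-07, and 0.999 with an estimated correlation), −0.44 and −0.32 in the 2 sets.

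Of 37 DNA replication genes 1 rose and 2 fell (1 and 2 adjusted over the list alone, 1 and 10 after quantile normalization). Mcm5 fell from 174 ± 40.8 to 82.7 ± 24.4, while Gins3, another replication factor, rose from 39.4 ± 13.8 to 90.7 ± 11.5. The Mcm5 call ended in replicates 4 to 6 (−0.788, adjusted p = 0.0897) and the Gins3 call in replicates 1 to 3 (0.922, adjusted p = 0.073). The list shift was −0.17 (adjusted p = 0.0297, and 0.999 with an estimated correlation), −0.24 and −0.11 in the 2 sets, and its call ended in 4 of 18 settings (adjusted p up to 0.199) and without PC12-ND6 with serum replicate 1 (0.0736). Of 26 glycolysis genes 9 rose and 2 fell (12 and 3 adjusted over the list alone, 11 and 5 after quantile normalization). Aldolase C (Aldoc) rose from 58.4 ± 18.5 to 258 ± 39.0, triosephosphate isomerase (Tpi1) from 934 ± 404 to 2224 ± 532, and Slc16a3 from 119 ± 26.5 to 302 ± 33.4. The glycolysis shift was 0.24 (adjusted p = 0.0297, and 0.999 with an estimated correlation), 0.27 and 0.21 in the 2 sets, and its call ended in 3 of 18 settings (adjusted p up to 0.178).

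**Figure D2:**
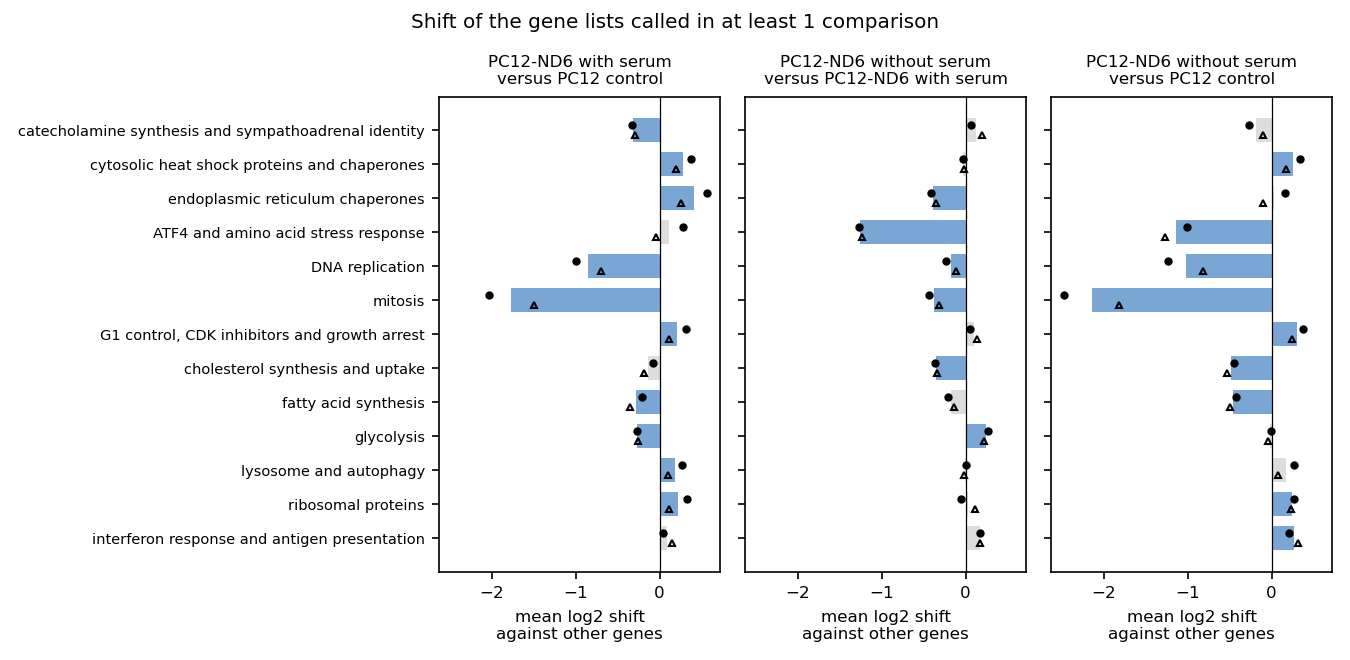
Mean log2 shift of each gene list against the other genes (horizontal axis) in the 3 comparisons, for lists called in at least 1 of them; blue bars passed camera with a preset correlation at an adjusted p under 0.05, and grey bars did not. Circles give the shift in replicates 1 to 3 and open triangles that in replicates 4 to 6. Mitosis lies at −1.77, −0.38 and −2.15 from left to right, and the ATF4 list at −1.26 for serum removal. No call held with an estimated correlation.

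Lists not called after serum removal still held genes that changed. Of 24 dense-core granule genes 5 rose and 0 fell (5 and 0 adjusted over the list alone, 5 and 0 after quantile normalization, list adjusted p = 0.143), with Vgf at 633 ± 157 against 150 ± 46.0 and adrenomedullin (Adm) at 2404 ± 485 against 809 ± 325. Of 38 synaptic vesicle genes 8 rose and 0 fell (8 and 0, 8 and 1, 0.15). Of 35 interferon genes 9 rose and 0 fell (9 and 1, 9 and 1, 0.0703). Of 35 pro-apoptotic genes 8 rose and 3 fell (9 and 3, 8 and 5, 0.997), led after Casp4 by the death-associated kinase Dapk1, which rose from 92.2 ± 29.4 to 314 ± 38.6. Of 29 anti-apoptotic genes 1 rose and 1 fell (1 and 1, 1 and 2, 0.237). Jun, an immediate early gene, rose from 184 ± 41.3 to 633 ± 131, in a list of 42 where 6 rose and 2 fell (9 and 4, 8 and 4, 0.912). The respiratory subunit Uqcrh rose from 522 ± 172 to 1305 ± 297, in a list of 69 oxidative phosphorylation genes where 4 rose and 0 fell (4 and 0, 9 and 6, 0.394). The proteasome subunit Psmd10 rose from 459 ± 124 to 1436 ± 147, in a list of 30 where 2 rose and 0 fell (2 and 0, 4 and 4, 0.73). Of 56 antioxidant genes 8 rose and 4 fell (10 and 4, 13 and 9, 0.778). Of 37 G1 control genes 8 rose and 2 fell (10 and 3, 11 and 7, 0.419). Of 37 neurite genes 7 rose and 2 fell (7 and 2, 7 and 8, 0.778). Of the markers of other cell types, 2 of 43 fibroblast markers rose (2 and 0 adjusted over the list alone, 3 and 1 after quantile normalization, list adjusted p = 0.169) and 1 of 32 leukocyte and endothelial markers (0 and 0, 1 and 0, 0.394), while 0 of 20 Schwann cell and glial markers (0.714) and 0 of 15 adrenal cortex markers (0.73) passed by limma, as deposited or after quantile normalization. Of 18 bHLH genes 2 rose and 0 fell (2 and 1 adjusted over the list alone, 2 and 2 after quantile normalization, 0.73). Of 22 catecholamine genes 3 rose and 1 fell (5 and 1, 4 and 3, 0.616). Of 42 ion channel genes 3 rose and 1 fell (3 and 1, 3 and 1, 0.584). Of 44 growth factors and receptors 4 rose and 3 fell (4 and 3, 3 and 5, 0.208). Of 46 mitochondrial biogenesis genes 3 rose and 1 fell (3 and 1, 6 and 11, 0.714). Of 40 heat shock genes 1 rose and 0 fell (1 and 0, 2 and 4, 0.778). Of 23 fatty acid genes 2 rose and 2 fell (2 and 2, 2 and 4, 0.237). Of 51 lysosome genes 3 rose and 0 fell (3 and 0, 8 and 5, 0.961). By limma 0 of 45 ribosomal protein genes passed, as deposited or after quantile normalization (0.73).

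Several of these lists were called in other settings, so their status after serum removal depends on the analysis. Synaptic vesicle genes were higher with the block of replicates 1 to 3 against 4 to 6 (shift 0.156, adjusted p = 0.0424), with replicate number as a block (0.0382), in replicates 1 to 3 (0.0463) and after quantile normalization with the actin ratio (0.0393). Dense-core granule genes were higher after loess normalization (adjusted p = 0.0336), among bright probe sets (0.00835), and after quantile normalization with the block (0.0444) or the actin ratio (0.0281). The interferon list was called higher with a floor (adjusted p = 0.0452), in replicates 1 to 3 (0.0463), without PC12-ND6 with serum replicate 2 (0.0337) and without the serum-free replicate 4 (0.04). Oxidative phosphorylation was called higher with array weights (adjusted p = 0.0102), in replicates 4 to 6 (0.0327) and without PC12-ND6 with serum replicate 1 (0.0164). Without that array growth factors (adjusted p = 0.0366) and fibroblast markers (0.0402) were called lower, as was fatty acid synthesis among bright probe sets (0.0336).

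After serum removal 1073 probe sets were higher and 297 lower, or 1500 and 1357 after quantile normalization. Higher calls were 52.5% of the total after quantile normalization in place of 78.3%. Of the probe sets called, 1322 were called in the same direction both ways. With a change of at least 1 the counts were 238 and 92, or 163 and 138 after quantile normalization. No overlap between the 6 and 6 arrays was found for 737 probe sets (4.65%, against 0.216% by chance). Replicates 1 to 3 alone gave 238 higher and 116 lower, and replicates 4 to 6 alone 848 and 268. The higher count was 1976 without PC12-ND6 with serum replicate 1 and 707 without the serum-free replicate 6. Replicate 1 with serum stood apart from the other 5 arrays of its group for Psph (592), Jun (263.5) and Gins3 (65.5), and the serum-free replicate 6 for Stc2 (82.0) and Fxyd6 (887).

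The comparison of serum-deprived PC12-ND6 with serum-grown control cells combined the difference between the lines with that between the media and any effect of the 48 h. It shares its arrays with both comparisons above. The largest increases were those of S100a6, to 3842 ± 505 from 122 ± 31.3 (log2 fold change 4.83, SE 0.27, adjusted p = 9.55e-11), Filip1l, to 805 ± 134 from 38.0 ± 12.8, Sprr1a, to 1950 ± 368 from 117 ± 24.3, and Lats2, to 256 ± 25.9 from 8.2 ± 6.4. Among the largest decreases, G0s2, an inhibitor of triglyceride lipase, fell from 3129 ± 401 to 112 ± 19.0 (−4.62, SE 0.15, adjusted p = 4.31e-14). Tns1, Boc and Ube2c changed by −4.17, −3.96 and −3.91. The size and order of the changes of Tns1, Boc and Lats2 again depend on the pseudocount. Mitosis genes fell in 38 of 39 cases (39 adjusted over the list alone and 39 after quantile normalization), ATF4 genes in 28 of 37, and DNA replication genes in 30 of 37.

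Mitosis shifted by −2.15 (adjusted p = 9.68e-51, and adjusted p = 0.0662 with an estimated correlation), with Ube2c at 59.3 ± 12.2 and Cdkn3 at 59.2 ± 13.1 against 1199 ± 530 and 916 ± 335 in the control. DNA replication shifted by −1.02 (adjusted p = 2.26e-22, and adjusted p = 0.351 with an estimated correlation), with 0 higher and 30 lower (0 and 32 adjusted over the list alone, 0 and 32 after quantile normalization). Tk1 and Mcm5 each fell by 2.47 on the log2 scale. The ATF4 list shifted by −1.14 (adjusted p = 1.84e-21, and adjusted p = 0.44 with an estimated correlation), with 1 higher and 28 lower (2 and 28 adjusted over the list alone, 4 and 28 after quantile normalization), and Psat1 stood at 214 ± 30.7 against 2252 ± 356. Of 22 cholesterol genes 0 rose and 9 fell (0 and 12 adjusted over the list alone, 1 and 12 after quantile normalization), led by the squalene epoxidase Sqle, at 83.8 ± 26.0 against 257 ± 113, and Insig1, at 253 ± 38.1 against 647 ± 175. Of 23 fatty acid genes 0 rose and 11 fell (1 and 12 adjusted over the list alone, 2 and 12 after quantile normalization), led by Mid1ip1, which promotes fatty acid synthesis, at 426 ± 67.6 against 1444 ± 653, and the elongase Elovl6, at 140 ± 29.3 against 459 ± 188. Cholesterol shifted by −0.49 (adjusted p = 9.99e-05, and 0.999 with an estimated correlation) and fatty acid synthesis by −0.46 (adjusted p = 0.000904, and 0.999 with an estimated correlation).

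Higher lists in this comparison were heat shock, G1 control, ribosomal proteins and interferon response. Of 40 heat shock genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, 16 and 2 after quantile normalization, shift 0.25, adjusted p = 0.0264, and 0.999 with an estimated correlation), with Hspb1 at 1988 ± 309 against 632 ± 144. Of 37 G1 control genes 11 rose and 6 fell (13 and 6 adjusted over the list alone, 16 and 7 after quantile normalization, shift 0.31, adjusted p = 0.035, and 0.999 with an estimated correlation), with Gadd45b changed by 2.50 on the log2 scale (SE 0.20, adjusted p = 1.86e-08) and Cited2 at 2363 ± 239 against 417 ± 72.4. Of 45 ribosomal protein genes 4 rose and 0 fell (4 and 0 adjusted over the list alone, 15 and 0 after quantile normalization, shift 0.25, adjusted p = 0.0047, and 0.999 with an estimated correlation), led by Rpl22 (log2 fold change 1.39, SE 0.16, adjusted p = 2.03e-06). Of 35 interferon and antigen presentation genes 7 rose and 0 fell (8 and 1 adjusted over the list alone, 11 and 2 after quantile normalization, shift 0.26, adjusted p = 0.0348, and 0.999 with an estimated correlation). They included RT1-S3, a class I histocompatibility gene, at 321 ± 48.0 against 97.8 ± 37.2, and the interferon-induced Rsad2, at 57.3 ± 13.2 against 12.2 ± 5.8. The interferon call ended after quantile normalization (adjusted p = 0.0671), in 6 other settings (up to 0.143), and without control replicate 5 (0.0596) or 6 (0.0694). In replicates 4 to 6 alone the heat shock (adjusted p = 0.109) and G1 (0.0681) calls ended, and in the fit of only the 2 groups the G1 call ended (0.0583).

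The remaining 21 lists were not called against the control. Of 51 lysosome genes 7 rose and 0 fell (9 and 0 adjusted over the list alone, 17 and 1 after quantile normalization, list adjusted p = 0.0897, and 0.0224 after quantile normalization). Of 30 endoplasmic reticulum chaperones 5 rose and 3 fell (5 and 3, 8 and 5, 0.778). Of 26 glycolysis genes 4 rose and 3 fell (5 and 4, 6 and 8, 0.801). Of 22 catecholamine genes 3 rose and 6 fell (3 and 6, 5 and 6, 0.252). Of 24 dense-core granule genes 3 rose and 2 fell (4 and 2, 6 and 3, 0.815). Of 18 bHLH genes 1 rose and 2 fell (2 and 2, 2 and 2, 0.654). Of 37 neurite genes 6 rose and 9 fell (6 and 9, 9 and 10, 0.961). Of 38 synaptic vesicle genes 6 rose and 5 fell (7 and 5, 9 and 5, 0.211). Of 42 ion channel genes 2 rose and 4 fell (2 and 4, 4 and 6, 0.282). Of 44 growth factors 4 rose and 5 fell (4 and 6, 5 and 6, 0.73). Of 56 antioxidant genes 8 rose and 5 fell (11 and 7, 20 and 9, 0.616). Of 46 mitochondrial genes 3 rose and 2 fell (3 and 2, 6 and 8, 0.778). Of 69 oxidative phosphorylation genes 2 rose and 4 fell (2 and 2, 12 and 11, 0.972). Of 30 proteasome genes 2 rose and 2 fell (2 and 2, 4 and 3, 0.801). Of 35 pro-apoptotic genes 8 rose and 3 fell (8 and 4, 11 and 6, 0.467). Of 29 anti-apoptotic genes 2 rose and 3 fell (3 and 3, 4 and 7, 0.714). Of 42 immediate early genes 6 rose and 2 fell (9 and 2, 11 and 6, 0.149). Of the markers of other cell types, 3 fibroblast markers rose and 4 fell (3 and 4, 3 and 5, 0.531), 0 and 1 of Schwann cells (0 and 1, 2 and 1, 0.972), 0 and 3 of leukocytes (0 and 3, 0 and 3, 0.252), and 0 of 15 adrenal cortex markers passed by limma as deposited and 1 after quantile normalization (0.99). The lysosome list was also called after loess normalization (adjusted p = 0.0318), after quantile normalization with the block (0.025) or the actin ratio (0.0163), in replicates 1 to 3 (0.00981), without the 4 arrays of highest actin ratio (0.0183) and without control replicate 6 (0.0413). In replicates 1 to 3 the immediate early list was called (adjusted p = 0.0187).

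The 2 sets of replicates together hold the arrays that gave the list calls, so they offer no independent check of direction. Shifts kept their direction in both sets of replicates for all 25 called lists of the 3 comparisons. For this comparison they were −2.48 in replicates 1 to 3 and −1.82 in replicates 4 to 6 for mitosis, −1.24 and −0.81 for DNA replication, −1.004 and −1.275 for the ATF4 list, −0.45 and −0.53 for cholesterol, and −0.42 and −0.49 for fatty acid synthesis. Those of the higher lists were 0.33 and 0.17 for heat shock, 0.37 and 0.24 for G1 control, 0.27 and 0.23 for ribosomal proteins, and 0.20 and 0.32 for interferon response. In all, 1295 probe sets were higher and 1206 lower than in the control, or 2499 and 2123 after quantile normalization, and 351 and 436 changed by at least 1 (351 and 432). No overlap between the 6 and 6 arrays was found for 1535 probe sets (9.67%, against 0.216% by chance). The 2 sets of replicates alone called 1056 higher and 519 lower in replicates 1 to 3 and 683 and 1902 in replicates 4 to 6.

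The comparisons overlapped in the probe sets that changed by at least 1 on the log2 scale. With and without serum, 82 were higher in PC12-ND6 than in the control and 260 lower, where independent lists would share 2.68 and 10.58. After quantile normalization 103 were higher and 228 lower. The 2 comparisons share the controls. With the control arrays split between the comparisons the counts were 87 and 249. S100a6, Lats2, Hmox1 and Atf3 were higher in both, and Chga, Thy1 and Uchl1 were lower with serum and stood at 643 ± 192, 147 ± 39.5 and 94.5 ± 24.3 without it. Across probe sets, which are not independent replicates, the fold changes correlated at 0.715, against 0.465 in simulations of unchanged groups, with a covariance of 0.143 against 0.013. Between the line difference and serum removal, 14 probe sets were higher and then lower (0.7 by independence), as were Myc and Hspa5, and 29 lower and then higher (5.78), as were Gstm1 and Vgf. In the same direction 7 were higher in both and 5 lower in both (1.82 and 2.23). After quantile normalization the opposite counts were 21 and 19, and those in the same direction 6 and 9. With no minimum size the opposite counts were 51 and 225 as deposited and 409 and 315 after quantile normalization. Which opposite count was larger thus depended on the scaling. With the arrays of PC12-ND6 with serum split, the opposite counts by at least 1 were 9 and 30 as deposited. The fold changes of these 2 comparisons correlated at −0.154 (−0.039 with those arrays split), with a covariance of −0.022. Simulations of unchanged groups that share those arrays gave −0.464 and −0.013, so these values do not settle whether the whole profile was partly reversed.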

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

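The tests of array brightness, that of the actin ratio against the 5S signal, and those of the bacterial control transcripts were chosen only after the result was seen. In 261 groups of 6 values, 16 (6.1%) held an array apart from the other 5 by Dixon's ratio (gap to the nearest value over the range, above its 95% critical value), where chance gives about 1 in 20. Of the 16, 9 were the highest value on PC12-ND6 with serum replicate 1, the array with the highest mean signal (328.8). Its ratios were 0.704 for Hspa5 (signal 5021, next 3506), 0.646 for Hspb1, 0.656 for Psph, 0.685 for Gins3, 0.658 for Jun, 0.692 for Cited2, 0.711 for Pdlim1, 0.767 for H1f2 and 0.630 for H2ac25. Replicate 6 without serum was highest for Mat1a (0.712), Fxyd6 (0.656) and Stc2 (0.690), and replicate 1 without serum for Tns1 (0.633, signal 7.0). In the control, replicate 3 was highest for Pdia2 (0.667, signal 1.6), replicate 4 for Vgf (0.759, signal 1199) and replicate 6 for Psmd10 (0.725, signal 583).

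The grouping of the arrays was tested against 99 other splits of the same 12 arrays into 6 and 6, drawn from the 462 possible, the real one included. Chance as the source of the number of calls is argued against in each comparison, since in 1 of 100 splits, the real one, the count was as large. Most of the 462 possible splits were not run, so a count as large among them cannot be excluded. PC12-ND6 with serum against control gave 1609 calls and the highest of the 99 others drawn 1574, serum removal 1370 and 875, and PC12-ND6 without serum against control 2501 and 792. After quantile normalization these were 3179 and 1516, 2857 and 258, and 4622 and 1378. The split of the same arrays into replicates 1 to 3 and 4 to 6, run apart from those drawn, gave 1418, 37 and 1030 calls as deposited and 1809, 1485 and 384 after quantile normalization. It exceeds the highest of those drawn in 3 of 6 cases and stays under the real split in each, which points to a structure of the arrays that is large but smaller.

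Replicates 4 to 6 differed from replicates 1 to 3 within each group, by 1044 higher and 1049 lower probe sets in the control after quantile normalization, 1056 and 921 in PC12-ND6 with serum, and 718 and 555 without serum. Overall brightness as the whole cause is argued against. After quantile normalization, deviations from the group means still correlated more within these sets than across them between arrays of different groups, by 0.45. A part of brightness is not ruled out, since as deposited 3161 were higher and 36 lower in the control. These counts were 161 and 51 in PC12-ND6 with serum and 112 and 9 without serum. In the control the mean signal was 281 in replicates 4 to 6 against 216 in replicates 1 to 3. It was 218 against 240 with serum and 243.0 against 245.5 without serum. RNA degradation as the whole cause is argued against: the variance of the difference without serum, where the actin ratio hardly differed (2.97 against 2.44), was 0.73 of that in the other groups (0.56 to 0.87 with 1 array left out). The 3' probe set of dap, an added control transcript, was also higher in replicates 4 to 6 than in replicates 1 to 3. Its signal was 453 ± 159 against 241 ± 4.25 in the control. It was 806 ± 265 against 490 ± 310 with serum and 774 ± 220 against 426 ± 76.4 without serum. A batch in culture, labelling or hybridization may remain, and no label gives one. At which of these steps the sets diverged was not tested. No biological explanation was tested, since the design names none for these sets.

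The control probe set for 5S ribosomal RNA was higher without serum, at 456 ± 126 against 76.0 ± 32.9 with serum and 46.2 ± 8.40 in the control (6.26-fold and 9.69-fold, exact permutation p = 0.00216, adjusted 0.026 over 24 tests of array measures). Over 114 tests of all 57 control probe sets its adjusted p against the control was 0.123. That reflects a limit of the test, since 0.00216 is the smallest p that 924 permutations can give. Among the other control probe sets, all 24 for the poly(A) transcripts dap, lys, phe and thr were higher on average than in the control, by 1.46-fold to 2.34-fold in PC12-ND6 with serum and 1.29-fold to 2.23-fold without serum. Their mean per array was higher by 0.63 on the log2 scale with serum (0.63 in replicates 1 to 3 and 0.64 in replicates 4 to 6, 5 of 6 arrays above the control median) and by 0.58 without (0.53 and 0.64, 6 of 6 arrays). These differences did not pass (exact permutation p = 0.0606 and 0.039, adjusted 0.121 over 4 tests). The 18 hybridization control probe sets differed by 0.06 and 0.12 (exact permutation p = 0.645 and 0.405). In replicates 1 to 3 and 4 to 6 these differences were 0.26 and −0.14 with serum, and 0.38 and −0.14 without serum. The small means thus came from differences of opposite sign. Unequal amounts of the added transcripts and a smaller share of mRNA in the total RNA of PC12-ND6 were not told apart by any test here, so both stay open. Brightness is argued against by a ratio of mean signals of 1.08, and RNA degradation by an actin ratio without serum of 0.75 times that with serum (0.67 to 0.87 with 1 array left out). Carry-over of RNA without a poly(A) tail cannot be told apart: histone probe sets had a median change of 0.21, under the 0.5 set beforehand as evidence against it, but that bound was wrong because 6 of 8 lay at or under a signal of 50, and 3 were called higher (H1f2, H2ac25 and H4cl1). A change in 5S ribosomal RNA itself with serum removal may also account for it and was not tested.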

How the results depend on the processing

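The analyses of replicates 1 to 3 or 4 to 6, those with that block, and those on the actin ratio were chosen after seeing the data. Named genes gave 323 results, and 0 reversed in any setting. All 323 kept their side of the threshold under quantile and loess normalization, the block of replicates 1 to 3 against 4 to 6, quantile normalization with that block, and quantile normalization with the actin ratio as covariate. Fewer passed with median centring (6 lost), pseudocounts 1 (23) and 64 (13), the floor (7), bright probe sets only (1 of 253), the trended prior (1), unequal variances (75), array weights (2), only the 2 groups compared (17), replicates 1 to 3 (86), replicates 4 to 6 (52) and without the 4 arrays of highest actin ratio (43). With 3 arrays per group the fewer samples limit the calls; otherwise the cause was not tested. With replicate number as a block 2 were lost. The numbers do not pair the arrays of different groups. As deviations from their group means, same-number arrays correlated at 0.211 and others of the same set at 0.227. Of 90 list results, 0 to 8 were lost and 0 to 6 gained in a setting, apart from camera with an estimated correlation (25 lost) and fry in place of camera (15 lost and 4 gained). The ribosomal list after serum removal, not called as deposited (0.029), reversed to −0.126 (adjusted p = 0.041) without those 4 arrays.

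Counts that moved by over 1.5 times are given in the order PC12-ND6 with serum against control, serum removal, and PC12-ND6 without serum against control. Scaling changes which arrays are bright, and moved counts as follows. Median centring gave 1384 higher in the first, 1359 lower in the second (150 higher and 144 lower by at least 1), and 1991 higher and 2162 lower in the third. Quantile normalization gave 1715 higher, 1357 lower, and 2499 higher and 2123 lower. Loess gave 1537 higher, 1362 lower (155 higher by at least 1), and 2340 higher and 2349 lower. Quantile normalization with the block gave 2196 higher and 1914 lower, 1957 and 1842 (140 lower by at least 1), and 2986 and 2605. With the actin ratio it gave 2033 and 1796, 1724 and 1609 (156 higher by at least 1), and 2857 and 2452.

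A pseudocount changes fold changes by construction: by at least 1, pseudocount 1 gave 235 higher, 388 higher and 153 lower, and 592 higher, with overlaps of 84 (opposite) and 31 (same direction, line difference and serum removal). Pseudocount 64 gave 46 higher and 211 lower, 112 and 54, and 146 and 256, with overlaps of 22, 3 and 176 (both against control). Bright probe sets only, fewer by construction, gave 281 higher (247 lower by at least 1), 232 higher by at least 1 in the third, and an overlap of 196. No minimum size gave overlaps of 276, 89 and 1014. Unequal variances gave 184 higher and 587 lower, and 527 higher in the second. Array weights gave 1875 lower, and 2699 higher and 498 lower in the second. Replicates 1 to 3 gave 415 lower (262 higher by at least 1), 238 higher and 116 lower, and 519 lower (598 higher by at least 1). Replicates 4 to 6 gave 197 higher and 1984 lower (76 higher by at least 1), and 683 higher and 1902 lower in the third (658 lower by at least 1). Without the 4 arrays there were 640 lower (220 higher by at least 1), and 539 higher in the second. Lists called were 0, 0 and 0 with an estimated correlation, and 6, 3 and 5 with fry. For weights, variances and those 4 arrays the cause was not tested.

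With 1 array left out the first comparison gave 317 to 535 higher and 882 to 1864 lower (by at least 1, 92 to 152 and 336 to 454), the second 707 to 1976 and 225 to 325 (201 to 324 and 74 to 114), and the third 1012 to 1552 and 972 to 1508 (307 to 405 and 383 to 517). Overlaps ran from 35 to 55 (opposite), 10 to 14 and 317 to 368, and lists called from 8 to 10, 6 to 8 and 8 to 9. The values 1864 and 1976 are those without PC12-ND6 with serum replicate 1, and 707 that without the serum-free replicate 6. No slide or scan batch is given, so that block was not run. About 31% of probe sets lay under a signal of 16, where changes are hard to tell from background.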

Other observations

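The scans of the other comparisons, the extent of the regions and the genes listed in them were chosen only after the scan of PC12-ND6 with serum against control was seen, and Pdlim1 and Tmem176b are named after their values were seen. For the genes near the floor, the tests of degradation and brightness were also chosen afterwards, in place of one whose outcome the selection of those genes had fixed. Genes of PC12-ND6 were shifted in blocks of neighbours along the chromosomes. In the gene order of the assembly GRCr8, 79 measured genes from Klhl18 to Ccr2 were higher than in the control by a mean of 0.37 on the log2 scale after quantile normalization, with 42 called higher and 4 lower (0.265 as deposited, with 18 and 4). Between Kcnj2 and Metrnl, 116 measured genes had a mean of −0.41, with 66 called lower and 4 higher (−0.517, 61 and 2 as deposited), and between Eftud2 and Dcaf7, 25 genes had a mean of −0.32, with 11 lower (−0.426 and 11). The means were 0.35 and 0.38 in replicates 1 to 3 and 4 to 6 for the higher block, and −0.44 and −0.38 for the larger lower block. Serum removal left the same blocks at 0.000 and −0.002. The 220 genes are 2.1% of the placed genes 7.9% of those called as deposited and 5.5% of those called after quantile normalization, where a larger share follows from the choice of regions with shifted genes.

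A candidate explanation is gain or loss of chromosome segments in the stable line. Over 25 neighbouring measured genes the lowest mean was −0.59 (Cygb to Cbx2), beyond 95% of 1000 random gene orders (limit −0.31, permutation p = 0.001, the smallest they can give), and the highest was 0.57 (limit 0.305, with the same p). Neighbours regulated together as a general feature of these cells are argued against, since serum removal gave at most 0.26 (permutation p = 0.17). Silencing of a whole segment in this line was not tested, nor was any effect of NeuroD6 on these segments, so both stay open. Among the genes of the report, Tk1, Fasn and Slc16a3 lie in the larger lower block and Rpl14 and Rpsa in the higher one.

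In PC12-ND6, 6 genes were near the floor on all 12 arrays (under a signal of 50) and above 150 on all 6 control arrays: Chrna3, Tns1, Rras2, Boc, Pdlim1 (296 in the control, 21.8 with serum) and Tmem176b (210 in the control, at most 25.4 in PC12-ND6). The reverse held for 0 genes. Loss of wide chromosome segments around these 6 genes as a set is argued against. The 60 nearest measured genes, pooled, lay 0.08 above random neighbours (one-sided permutation p = 0.9). A loss around 1 of the genes, or one that ends before its nearest measured neighbours, could not be seen in that pooled mean. Degraded RNA is argued against, since the actin ratio of the arrays without serum, where these genes are also near the floor, was 0.87 times that of the control (0.80 to 0.997 with 1 array left out). Dimmer arrays are argued against by a ratio of mean signals there of 0.99 (0.94 to 1.028). Silencing in the cell or cells that founded the line, or an effect of NeuroD6, may account for these genes, and neither was tested.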
